A study of Danio rerio with 24 samples.

How the data were processed

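RNA sequencing was carried out on whole zebrafish embryos at 4 days post fertilization, per the labels' protocols. Embryos were kept at 28.5 °C and given a heat treatment of 1 h at 2 and again at 3 days, which switches on a transcriptional driver placed behind an hsp70l promoter. For each targeted line, 3Tg embryos carried the CRISPR components and a guide RNA, and their 2Tg siblings carried the components with no guide RNA. There were 4 lines (smn1, tardbp with tardbpl, lin28a, sox9b), 8 groups, 3 replicates in each group and 24 libraries. RNA was extracted with TRIzol or RNAiso Plus and libraries were made by a sequencing company, per the labels' protocols.

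The deposited values are in TPM, a length-scaled share of transcripts, per gene, in 1 table for each line, per the file headers. Trimmomatic 0.39, STAR 2.7.10b, Salmon 1.10.1 and the genome builds GRCz11 and danRer11 are named in the submitters' processing notes, which give neither the role of each tool nor their order. No read counts were used here, so the depth of each library is unknown and no counting interval is given. Each table holds 25432 genes. The TPM of 23 libraries sum to between 983631 and 990345, and those of the tardbp 3Tg replicate 3 library sum to 778190. The values of 10 libraries are written with 6 decimals and those of the other 14 with 6 significant digits. Both formats occur within the smn1 table (6 decimals in 2Tg replicates 1 and 2 and 3Tg replicate 1) and within the tardbp table (6 decimals in 2Tg replicate 2). The smn1 table also has 13 unnamed columns, which hold no sample values and were not used. Genes were identified by their Ensembl identifier, since 684 entries repeat a symbol.

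Each line was analysed alone, 3 libraries against 3, as log2(TPM + 1) with no scaling between libraries. Genes with a TPM of at least 1 in at least 3 of the 6 libraries were tested with limma (linear model with an empirical Bayes variance prior that follows a trend in abundance; two-sided), and p was adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Changes are given as 3Tg minus 2Tg on the log2 scale. Adjusted p values without another name are from limma. The 5 targets also have an adjusted p over those 5 alone and an exact permutation test, whose smallest two-sided p with 3 against 3 is 0.1, so it could not pass the threshold. Shares of the TPM (mitochondrially encoded genes; the 100 most abundant genes) were compared with the same exact test.

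Gene lists, 35 in all, covering tissue markers, stress and signalling pathways and complexes, were written down beforehand. Each was tested with camera (limma) at a preset correlation of 0.01, which compares a list with all other genes, adjusted over the 35 lists of a line. Camera with an estimated correlation and fry (limma), which asks whether a list moves at all, were alternatives. Members of a list that passed with the adjustment made over the list alone are reported as such. Where a list is said to be above or below the other genes, this refers to camera at the preset correlation.

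The targets and the paralogs lin28b and sox9a are named in every line. In each line the 12 highest and 12 lowest fold changes among called genes with no overlap between groups and with a gene name other than a clone code were to be named; where fewer than 5 passed, the 8 such genes of smallest p are given as values. This rule, the lists, the tests and most alternatives were fixed before the data were examined. Members named as examples of a list were chosen after their values were seen.

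Alternatives were a pseudocount of 0.1 or 5, no filter or a TPM minimum of 5, median centring, quantile normalization, totals rescaled without mitochondrially encoded genes and the 20 most abundant genes, a replicate block, library weights, a robust or an untrended variance prior, 1 fit over all 24 libraries, other thresholds, and each library left out in turn. Chosen after the data were seen were the number format as a covariate in smn1, median centring without tardbp 3Tg replicate 3, the gene list tests under centring, rescaling and leave-outs, the differences between lines under centring or without tardbp 3Tg replicate 3, the target ratios in leave-outs, and the genes shared by smn1 and tardbp under centring or without that library. Differences between lines were tested with 1 limma fit over the 24 libraries for the 6 pairs of lines. The tests were tried on simulated data. For each table, new values were drawn for every gene, independently, from a normal distribution with that gene's mean and its spread within groups. Changes were then added to 200 genes with a mean log2 value above 2. These draws hold no correlation between genes and no shift shared by a library, unlike the real data, so the rates below may not carry over. Of genes changed by 2 on the log2 scale, the test recovered 63% in smn1, 0% in tardbp, 66% in lin28a and 91% in sox9b; of those changed by 1, it recovered 17%, 0%, 5% and 49%.

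Gene order came from an annotation of a genome assembly other than the submitters', matched by symbol, and was used for neighbourhood only. The planned tests by chromosome and by position, and the distance of genes from a target, were not run, for want of an annotation of the submitters' assembly; the 3 genes on either side of smn1, tardbpl and lin28a and the 3 on 1 side of sox9b were examined in their place. Computation used R 4.3.3, limma 3.58.1, statmod 1.5.0, Python 3.11.15 and matplotlib 3.10.9.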

Results

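The data are TPM of 25432 genes in 24 libraries of whole zebrafish embryos at 4 days post fertilization, from 4 transgenic lines with 3 libraries of 3Tg embryos, which carry a guide RNA, and 3 of 2Tg siblings, which lack it. The question was how well, and how selectively, a heat-induced system lowered smn1 or tardbp with tardbpl (knockdown) or raised lin28a or sox9b (activation). Depth is unknown. In 23 libraries the listed TPM summed to 98.4% to 99.0% of the total to which TPM are scaled; in tardbp 3Tg replicate 3 they summed to 77.8%. Values are mean ± SD in TPM with n = 3 unless stated.

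As deposited, each of the 5 targets moved in the direction its line was built for, with no overlap between the 3 libraries of each group. Of all genes tested, 19.2% showed no overlap in smn1, 29.2% in tardbp, 6.56% in lin28a and 4.75% in sox9b, where chance gives 10%. In the knockdown lines smn1 stood at 58.6% of its 2Tg level, tardbp at 54.5% and tardbpl at 53.1%. In the activation lines lin28a was 5.93-fold (3.65-fold without 3Tg replicate 2) and sox9b 1.98-fold its 2Tg level. For lin28a that 2Tg level was low, at 0.801 TPM, and its 3Tg mean of 4.76 lay below the 2Tg means of the other lines. smn1 encodes the survival motor neuron protein, tardbp and its paralog tardbpl encode TDP-43 proteins that bind RNA, lin28a encodes an RNA-binding protein that restrains let-7, and sox9b encodes a transcription factor of cartilage and neural crest. As deposited, all 5 passed limma with adjustment over the 5 targets alone, and none passed with adjustment over all genes. The adjustment over the 5 targets was not repeated after median centring. Ranked by p among all genes tested in its line, sox9b was at place 3, lin28a 16, smn1 267, tardbpl 1682 and tardbp 2109. The exact permutation p was 0.1 for each, the smallest possible. For tardbp, 3Tg replicate 3 overlapped with 2Tg after rescaling. Rescaled without 3 genes abundant there, that library held 110.9 TPM of tardbp, within the 2Tg range of 110.1 to 147.8. 3Tg replicates 1 and 2, at 75.7 and 81.2 TPM after that rescaling, stayed below this range. With 3Tg replicate 3 left out, tardbp and tardbpl differed by −0.67 and −0.72 on the log2 scale. After median centring with all libraries kept, they differed by −0.43 and −0.47, with adjusted p = 0.485 and 0.475 over all genes in limma. The pass of these 2 targets thus holds for the unscaled values only.

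**Figure D1:**
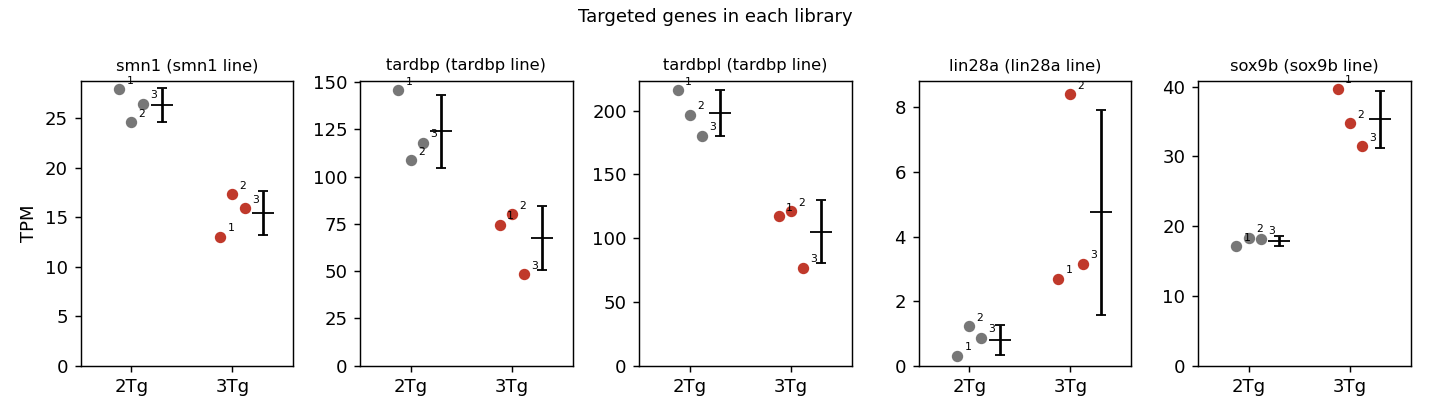
TPM of each targeted gene in the 2Tg and 3Tg libraries of its own line; points are libraries, numbered by replicate, and the black mark is the mean with its SD (n = 3). The 3Tg libraries of smn1 lie at 13.0 to 17.3 TPM and those of sox9b at 31.5 to 39.7 TPM, apart from their 2Tg libraries.

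In the smn1 line, the smn1 transcript (ENSDARG00000018494) was 26.3 ± 1.69 in 2Tg and 15.4 ± 2.19 in 3Tg. Of 24 heat shock genes 19 were lower in 3Tg by sign, 6 of which fell over the list alone, and genes of photoreceptors, intestine, nervous system and muscle were mostly higher by sign. hsp70l, a heat-inducible chaperone whose promoter drives the system, stood at 260.5 ± 49.7 in 2Tg and 15.5 ± 10.9 in 3Tg. The smn1 3Tg libraries (7.37 to 27.9 TPM) lay within the range of tardbp 2Tg (4.55 to 38.3). The smn1 2Tg libraries (231 to 318) lay above every 2Tg library of tardbp and lin28a (6.45 to 13.8), while sox9b 2Tg ran from 20.1 to 464. The difference may thus lie in a high 2Tg level as much as in a low 3Tg level. gnat2, the cone transducin of phototransduction, stood at 84.7 ± 9.11 in 2Tg and 191 ± 41.9 in 3Tg. For smn1 the log2 fold change was −0.74 (SE 0.193), with adjusted p = 0.00776 over the 5 targets and 0.340 over all genes in limma. No gene of the 19660 tested passed limma over all genes; 2421 had an unadjusted p under 0.05 (1154 higher, 1267 lower; after median centring 1456 higher, 1014 lower), where 983 are given by chance, and the smallest adjusted p was 0.0692. Without 3Tg replicate 3, 2 genes passed, hsp70l among them with adjusted p = 0.00691. The groups did not overlap in 3770 genes, 19.2%, where chance gives 10%.

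Of the 24 heat shock genes tested in smn1, 6 fell when adjusted over the list alone and 18 did not pass; none passed over all genes. The 6 were hsp70l (log2 −4.17, SE 0.418), hsp70.1 (−3.30), hsp70.2 (−2.43), hsp70.3 (−2.28), hspb1 (−1.72) and dnajb1b (−1.36), which encode chaperones or their partners. hspb1, a small heat shock protein, went from 4854 ± 1968 to 1476 ± 620.0, and hsp70.2 from 126 ± 19.0 to 23.9 ± 11.2. The list lay below the other genes (median −0.93, or −0.89 relative to all genes, adjusted p = 8.12e-06; adjusted p = 0.317 with an estimated correlation). Relative to all genes the median was −0.43 without 3Tg replicate 1, −0.55 without 2Tg replicate 1, −0.57 without 3Tg replicate 3 and −1.51 without 3Tg replicate 2, and the list passed at the preset correlation with each library left out (highest adjusted p = 0.00596). Between 5 and 6 members fell with any of 5 libraries left out, and 16 fell and 1 rose without 3Tg replicate 2. Within the libraries of 6 decimals the hsp70l difference was −4.80, and within those of 6 significant digits it was −4.08, while the list median was −1.61 and −0.47.

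**Figure D2:**
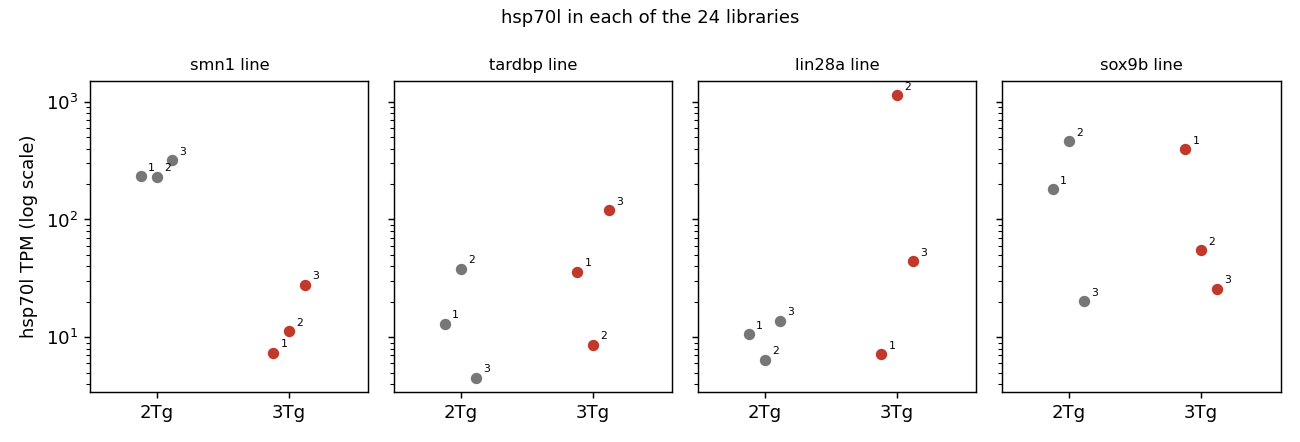
TPM of hsp70l in each of the 24 libraries, on a log scale; points are libraries, numbered by replicate, in the 2Tg and 3Tg groups of the 4 lines. In smn1 every 2Tg library lies above every 3Tg library, and over all lines the values run from 4.55 to 1137 TPM.

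Photoreceptor genes lay above the other genes in smn1 3Tg embryos, with a list median of 0.87 and 34 of 36 members higher by sign (adjusted p = 6.87e-14; adjusted p = 0.196 with an estimated correlation). Adjusted over the list alone, 14 of 36 rose. Among them were gnat2 (1.15), prph2a (0.98), which shapes the outer segment, and the short-wave cone opsins opn1sw2 (142 ± 23.5 to 284 ± 56.9) and opn1sw1 (379 ± 66.5 to 742 ± 199). That number was 0 without 2Tg replicate 1 or without 3Tg replicate 2 and 3 without 2Tg replicate 2. gnat2 differed by 0.86 within the libraries of 6 decimals and by 1.25 within the others, and the list median by 0.82 and 0.54.

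Markers of gut organs and clock genes lay above the other genes as well in smn1: the exocrine pancreas list had a median of 1.64 (adjusted p = 1.33e-06), the intestine list 1.28 (8.96e-11) and the circadian clock list 0.69 (1.44e-06). With an estimated correlation the adjusted p values were 0.508, 0.322 and 0.322. The libraries of 1 group differed widely: ela2, a pancreatic elastase, was 19.2, 1188 and 27.6 TPM in the 2Tg libraries and 169, 990.5 and 2281 in 3Tg. Of 24 intestinal genes, slc10a2, the ileal bile acid transporter, rose over the list alone (3.31 ± 0.888 to 10.2 ± 3.43, log2 1.35), and no member of the other two lists passed; after median centring 4 intestinal genes rose. Relative to all genes the exocrine pancreas median was 1.69, but 2.79 without 2Tg replicate 2, 2.57 without 3Tg replicate 1 and 1.07 without 3Tg replicate 3, and the clock median was 0.74, but 0.48 without 3Tg replicate 2. Without 2Tg replicate 2, 22 exocrine pancreas and 17 intestinal genes rose; without 3Tg replicate 1, 17 clock and 13 intestinal genes did and 1 clock gene fell. No intestinal gene passed without 2Tg replicate 1, 3Tg replicate 2 or 3Tg replicate 3. The intestine median was 0.49 within the libraries of 6 decimals and 1.73 within the others.

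The nervous system and muscle lists of smn1 had smaller medians, of the same sign. Neurons had a median of 0.33 (adjusted p = 2.02e-06), glia 0.46 (2.02e-06), motor neuron and neuromuscular junction genes 0.31 (2.61e-04) and skeletal muscle contractile genes 0.21 (2.58e-04), all 4 with adjusted p = 0.196 with an estimated correlation. No member passed over its list alone, except 3 glial genes without 2Tg replicate 2. The synaptic vesicle sensor syt1a was 61.2 ± 7.004 and 101 ± 14.8, the glial glutamate transporter slc1a2b 126 ± 8.23 and 202 ± 27.9, the neurofilament nefma 20.1 ± 2.92 and 28.9 ± 0.953, and the muscle parvalbumin pvalb4 949 ± 75.1 and 1509 ± 157 in 2Tg and 3Tg. Against the direction of its list, desma, the intermediate filament of muscle, was 352 ± 77.1 and 205 ± 44.1.

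The partners of SMN in assembling spliceosomal particles lay below the other genes in smn1 3Tg embryos: 20 of 21 genes of the SMN complex and Sm core list were lower by sign, with a median of −0.42 (adjusted p = 1.30e-05; adjusted p = 0.508 with an estimated correlation). No member passed over the list alone, but 3 fell without 3Tg replicate 2 and 1 without 3Tg replicate 1. The Sm protein gene snrpe was 215 ± 48.9 in 2Tg and 106 ± 50.9 in 3Tg, coil, which encodes the Cajal body scaffold coilin, was 7.14 ± 1.06 and 3.94 ± 0.791, and gemin5 was 6.39 ± 0.406 and 4.04 ± 0.941. Relative to all genes the list median was −0.38, and −0.61 without 3Tg replicate 1. It was −0.26 within the libraries of 6 decimals and −0.69 within the others.

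Among the remaining smn1 lists, unfolded protein response genes lay below the other genes (median −0.57, adjusted p = 0.0125). Above them lay cartilage (0.25, 3.40e-04), pluripotency and neural progenitor genes (0.25, 0.00494), endothelium (0.30, 0.00680), immediate early genes (0.27, 0.00680), neural crest and pigment cells (0.24, 0.00844), bone (0.07, 0.0152), muscle stress (0.28, 0.0343), keratinocytes (0.17, 0.0381) and cytosolic ribosomal proteins (0.08, 0.0435). With an estimated correlation the adjusted p was 0.322 for muscle stress, 0.786 for ribosomal proteins and 0.508 for the other 8. Over the list alone, 3 bone genes rose: ihha (2.78 ± 0.250 to 6.87 ± 0.561), a hedgehog ligand of growing cartilage, ifitm5 (5.01 ± 2.196 to 14.6 ± 4.50) and entpd5a (1.89 ± 0.523 to 4.195 ± 0.340), both of bone-forming cells. No bone gene passed without 2Tg replicate 1 or 3Tg replicate 2. The immediate early gene nr4a1 rose over its list alone (4.47 ± 0.453 to 11.13 ± 2.83), and no immediate early gene did with any library but 3Tg replicate 1 left out, where 2 did. Each of these 10 lists lost its call with at least 1 library left out. The highest adjusted p was 0.142 for the unfolded protein response and 0.887 for ribosomal proteins without 3Tg replicate 3, 0.195 for cartilage, 0.155 for pluripotency and 0.334 for endothelium without 3Tg replicate 1, 0.594 for immediate early genes without 3Tg replicate 3, 0.173 for neural crest and 0.435 for keratinocytes without 2Tg replicate 2, and 0.105 for bone and 0.401 for muscle stress without 3Tg replicate 2. Over the leave-outs the medians relative to all genes ranged from −0.76 to −0.25 for the unfolded protein response, 0.09 to 0.61 for cartilage, 0.06 to 0.55 for neural crest, 0.12 to 0.48 for bone, 0.06 to 0.43 for immediate early genes, 0.20 to 0.53 for endothelium, 0.19 to 0.42 for pluripotency genes, 0.26 to 0.45 for muscle stress, 0.10 to 0.31 for keratinocytes and 0.02 to 0.25 for ribosomal proteins. The other 15 lists did not pass (adjusted p 0.0532 to 0.760); camera gave the let-7 and inflammation lists a positive sign although their medians were 0.00 and −0.09.

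The 8 genes of smallest p in smn1, among those with a gene name other than a clone code, did not pass limma over all genes. Besides hsp70l (adjusted p = 0.0692), hsp70.2 and hsp70.3 (203 ± 37.1 and 42.5 ± 16.6), both 0.116, they were PCP4 (9.41, 4.48 and 8.27 TPM in 2Tg, listed at 0 in all 3 libraries of 3Tg), DYNLT1 (6.14 ± 0.359 in 2Tg; 0.661, 0 and 0 in 3Tg; adjusted p = 0.0741), hcst (17.9 ± 3.80 and 4.13 ± 0.198, 0.0741), echdc3 (16.1, 7.52 and 4.08 in 2Tg, listed at 0 in 3Tg) and ace (11.9 ± 0.781 and 31.5 ± 4.83, 0.171). DYNLT1 encodes a dynein light chain and ace encodes angiotensin-converting enzyme.

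In the tardbp line, tardbp (ENSDARG00000040031) was 124 ± 19.3 in 2Tg and 67.6 ± 17.0 in 3Tg, and tardbpl (ENSDARG00000004452) was 198 ± 17.99 and 105 ± 24.6. The hatching enzyme genes he1.2 and he1.1 were lower in 3Tg than in 2Tg, whose levels lay above those of every library of the other lines. Cell cycle, globin and spliceosomal assembly genes were low in 3Tg, and pancreatic, intestinal and clock genes were high in 2 of the 3 3Tg libraries. The median of all genes was −0.45 in this line, so that list values are also given relative to it. In 3Tg replicate 3, zgc:158463, FO704772.3 and AL935186.10 together made up 34.3% of the nominal TPM total, against 0.229% to 0.569% in the other 5 libraries, and 97.5% of genes lay below the mean of those 5.

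The log2 fold change was −0.89 (SE 0.398) for tardbp and −0.93 (SE 0.398) for tardbpl, with adjusted p = 0.0384 and 0.0382 over the 5 targets and 0.352 and 0.351 over all genes in limma. After median centring they were −0.43 and −0.47 (adjusted p = 0.485 and 0.475 over all genes in limma). Without 3Tg replicate 3 they were −0.67 and −0.72. Rescaled without those 3 abundant genes, 3Tg replicate 3 held 110.9 TPM of tardbp, within the 2Tg range of 110.1 to 147.8, while the other two 3Tg libraries held 75.7 and 81.2. tardbpl stood at 176.0 there, below the 2Tg range of 183.6 to 219.2 and above the other two 3Tg libraries at 119.1 and 122.6.

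Of 19336 genes tested in tardbp, 2 passed limma, both lower; 2657 had an unadjusted p under 0.05 (172 higher, 2485 lower; 967 by chance). After median centring, no gene passed, 2013 had an unadjusted p under 0.05 and 59.5% of those were higher, against 6.47% as deposited. The groups did not overlap in 29.2% of genes, where chance gives 10%. With 1 library left out the number of called genes was 26, 136 and 176 without 2Tg replicates 1, 2 and 3, and 2, 3 and 0 without 3Tg replicates 1, 2 and 3.

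he1.2 and he1.1 encode the enzymes with which the embryo digests its egg envelope. he1.2 was 158, 36.7 and 39.7 TPM in 2Tg and 5.41, 2.77 and 4.27 in 3Tg (log2 −3.64, SE 0.507, adjusted p = 0.0195 in limma), and he1.1 was 329, 60.4 and 109 in 2Tg and 15.11, 9.22 and 9.84 in 3Tg (−3.43, SE 0.512, adjusted p = 0.0244). After median centring the fold changes were −3.17 (SE 0.612) and −2.97 (SE 0.595), a drop within 1 SE beside a larger SE, and over the leave-outs they ranged from −4.00 to −2.96 and from −3.97 to −2.76. Both lost the call after centring (0.475 for each) and without 3Tg replicate 3 (0.137 and 0.149), and also with a pseudocount of 0.1, with no filter, after quantile normalization and with the rescaled total. Over the hatching gland list alone, these 2 of 6 genes fell, after centring as well, and ctsl.1, a cathepsin, rose (1.97). That list as a whole did not pass (adjusted p = 0.134). These genes also varied within groups of other lines: he1.1 was 27.96, 0.221 and 30.9 TPM in smn1 2Tg and 0.523, 2.89 and 33.0 in lin28a 3Tg. The highest values in the other lines were 57.7 TPM for he1.1 and 35.4 for he1.2, both in smn1 3Tg replicate 1. Every tardbp 2Tg library lay above these values, while the tardbp 3Tg libraries lay within the range of the other lines.

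**Figure D3:**
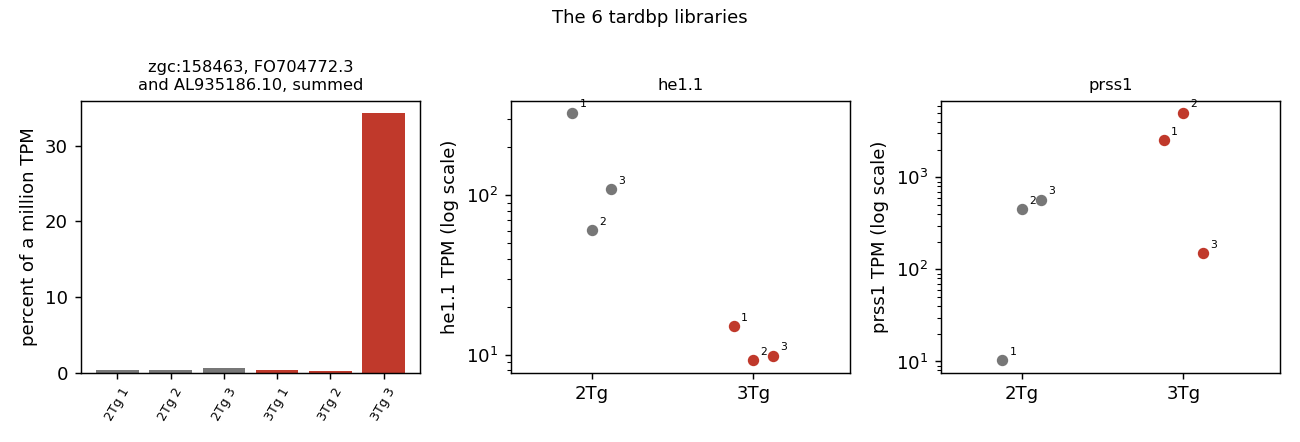
Left, the summed share of zgc:158463, FO704772.3 and AL935186.10 in each tardbp-line library, in percent of the nominal TPM total; middle and right, TPM of he1.1 and prss1 on log scales, with libraries as points numbered by replicate. The share is 34.3% in 3Tg replicate 3 and at most 0.569% elsewhere, and prss1 in that library (151 TPM) lies far below the other two 3Tg libraries.

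Digestive gland genes stood out in the tardbp line. The exocrine pancreas list had a median of 2.82, or 3.27 relative to all genes (adjusted p = 4.10e-43; adjusted p = 0.487 with an estimated correlation), and over the list alone 23 of 26 genes rose. The member that fell was ptf1a (−1.04), a transcription factor of pancreatic progenitors; no member fell with any library but 2Tg replicate 2 left out. The digestive enzymes were close to 0 in 2Tg replicate 1 and high in 3Tg replicates 1 and 2: amy2a, pancreatic amylase, was 0, 31.8 and 57.1 TPM in 2Tg and 333, 860.2 and 12.4 in 3Tg, and prss1, a trypsin, was 10.3, 452 and 572 in 2Tg and 2532, 5023 and 151 in 3Tg. None rose without 3Tg replicate 1 or without 3Tg replicate 2, and none did after median centring. The number that rose was 14 without 2Tg replicate 1, 24 without 2Tg replicate 2 or 3 and 23 without 3Tg replicate 3. The intestine list had a median of 0.87, or 1.32 relative to all genes (adjusted p = 5.62e-17; adjusted p = 0.631 with an estimated correlation), with no member passing over the list alone; 13 rose without 2Tg replicate 2, 2Tg replicate 3 (where 1 fell) or 3Tg replicate 3, and 2 without 2Tg replicate 1. The median relative to all genes was 1.88 for exocrine pancreas and 0.87 for intestine without 2Tg replicate 1. fabp6, the ileal bile acid binding protein, was 0, 164 and 145 in 2Tg and 784, 674 and 46.6 in 3Tg.

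Clock genes of the tardbp line followed the same libraries. The list median was 0.60, or 1.05 relative to all genes (adjusted p = 1.52e-13; adjusted p = 0.631 with an estimated correlation), and no member of 33 passed over the list alone as deposited, while 9 rose after median centring. Without 3Tg replicate 2 the median relative to all genes was 0.70. nr1d1, a repressor in the clock loop, was 1.13, 3.60 and 3.28 TPM in 2Tg and 46.6, 76.1 and 1.44 in 3Tg, and per1a was 0.723, 1.00 and 0.485 in 2Tg and 6.59, 13.7 and 0.688 in 3Tg. Without 3Tg replicate 3, 20 clock genes rose and 3 fell; 2 rose without 2Tg replicate 1 and 4 without 2Tg replicate 2 or 3.

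Cell cycle genes were low in the tardbp 3Tg libraries: all 34 members were lower by sign, with a median of −1.18, or −0.73 relative to all genes (adjusted p = 1.47e-14; adjusted p = 0.631 with an estimated correlation). Over the list alone 21 of 34 fell, among them cdk1 (53.5 ± 28.8 to 14.9 ± 5.65), the mitotic kinase, plk1 (57.3 ± 35.5 to 14.2 ± 6.93), mki67 (46.2 ± 24.03 to 13.4 ± 4.11) and aurka (24.4 ± 6.04 to 6.20 ± 1.92). Without 2Tg replicate 1, in which cdk1 stood at 86.8, 1 of 34 fell, and after median centring none did. Without 3Tg replicate 2 the median relative to all genes was −0.42.

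Globin and red cell genes of the tardbp line had a median of −0.99, or −0.54 relative to all genes, with all 28 lower by sign (adjusted p = 3.03e-06; adjusted p = 0.631 with an estimated correlation). The 4 that fell over the list alone were the globins hbba2 (18.6 ± 6.48 to 3.53 ± 4.01), hbaa1 (109 ± 34.5 to 34.6 ± 20.95), hbbe3 (−2.996) and hbae5 (−1.89). None fell without 3Tg replicate 1 or after centring, 1 without 3Tg replicate 2, 6 without 2Tg replicate 1, 7 without 2Tg replicate 2, 9 without 2Tg replicate 3 and 13 without 3Tg replicate 3 (6 after centring as well). The median relative to all genes was −0.24 without 2Tg replicate 1 and −0.26 without 3Tg replicate 2.

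The SMN complex and Sm core list was lower in the tardbp line too, with a median of −0.89, or −0.43 relative to all genes (adjusted p = 1.83e-05; adjusted p = 0.722 with an estimated correlation), and 9 of 22 fell over the list alone. They included snrpf (124 ± 55.2 to 34.9 ± 16.2), snrpb (316 ± 91.8 to 131 ± 11.4) and prmt5 (25.5 ± 3.42 to 10.3 ± 2.90), which methylates Sm proteins. None fell after centring; 13 fell without 3Tg replicate 3 (0 with centring as well) and at most 2 with any other library left out, with 0 without 2Tg replicate 2 and 1 rising without 2Tg replicate 3. The median relative to all genes was −0.25 without 2Tg replicate 1 and −0.26 without 3Tg replicate 2. Genes linked to amyotrophic lateral sclerosis or to TDP-43 had a median of −0.67, or −0.22 relative to all genes (adjusted p = 0.0184; adjusted p = 0.899 with an estimated correlation), and no member passed; without 3Tg replicate 3, 9 fell as deposited and 0 after median centring. fus, another RNA-binding protein of that disease, was 147 ± 15.12 in 2Tg and 63.4 ± 3.22 in 3Tg, hnrnpa0a was 215 ± 22.2 and 89.8 ± 7.25, and tia1 65.5 ± 12.6 and 28.1 ± 5.82. Without 2Tg replicate 1 the adjusted p of that list was 0.228, without 2Tg replicate 3 it was 0.0554 and without 3Tg replicate 2 it was 0.0840. Its median relative to all genes ranged over the leave-outs from −0.36 to −0.09.

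Relative to all genes, these lists were also higher in tardbp 3Tg embryos: photoreceptors (0.78, adjusted p = 6.38e-12), inflammation (0.71, 2.74e-11), lens (0.58, 3.70e-09), immediate early genes (0.50, 1.53e-04), leukocytes (0.42, 0.00122), heat shock (0.36, 0.00122), glia and muscle stress (0.23 each, 0.0170), interferon response (0.42, 0.0184), neurons (0.29, 0.0184) and cytosolic ribosomal proteins (0.20, 0.0224). The raw medians of the last 7 lists were below 0, though above 0 without 3Tg replicate 3, and so was the mean of the immediate early list (−0.01). Lower relative to all genes were cartilage (−0.20, 0.0170), pluripotency (−0.21, 0.0184) and neural crest (−0.26, 0.0325). With an estimated correlation none of the 35 lists passed (lowest adjusted p = 0.487). After median centring 5 lens genes and 1 inflammation gene rose over their lists alone, where none did as deposited. Over the leave-outs the medians relative to all genes ranged from 0.16 to 1.205 for photoreceptors, 0.20 to 1.08 for inflammation, 0.30 to 0.61 for immediate early genes, 0.10 to 0.48 for neurons and −0.43 to −0.08 for cartilage. They ranged from 0.15 to 0.51 for heat shock, 0.17 to 0.42 for glia, 0.14 to 0.34 for muscle stress, 0.23 to 0.46 for the interferon response, 0.09 to 0.32 for ribosomal proteins, −0.34 to −0.06 for pluripotency and −0.39 to −0.09 for neural crest. Over the cartilage list alone 3 of 38 fell: hapln1a (70.5 ± 16.3 to 22.8 ± 9.06), a link protein of cartilage matrix, col9a1b (119.9 ± 27.1 to 44.2 ± 12.1) and CYTL1 (−1.95). That number was 0 after median centring, 8 without 3Tg replicate 3 (0 with centring as well), 1 without 2Tg replicate 1 or 3Tg replicate 2 and 0 without 2Tg replicate 2. Of all 21 lists past the test, 8 kept the call with every library left out (SMN complex, cell cycle, lens, exocrine pancreas, intestine, erythrocytes, leukocytes and clock). For the others, the highest adjusted p without 1 library was, without 2Tg replicate 1, 0.235 for photoreceptors, 0.520 for neurons, 0.568 for pluripotency and 0.421 for neural crest; without 2Tg replicate 3 it was 0.361 for heat shock, 0.157 for immediate early genes and 0.163 for the interferon response. It was 0.0909 for inflammation without 3Tg replicate 3, 0.123 for glia and 0.505 for ribosomal proteins without 3Tg replicate 1, and 0.210 for muscle stress and 0.263 for cartilage without 3Tg replicate 2. The other 14 lists did not pass (adjusted p 0.0574 to 0.833).

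Besides he1.2 and he1.1, the genes of smallest p in the tardbp line, clone codes left aside, did not pass limma over all genes. They were VMAC (1.97, 2.47 and 7.20 TPM in 2Tg, listed at 0 in 3Tg), cdc20 (52.5 ± 27.0 and 9.85 ± 4.68, adjusted p = 0.239), ankrd10a (14.6 ± 2.01 and 2.97 ± 2.19, 0.267), hbba2 (0.299), aurka (0.329) and tmem26a (5.56 ± 0.817 and 0.936 ± 0.602, 0.329). Among the other targets and paralogs in this line, lin28a was 6.32 ± 1.68 and 1.85 ± 1.25 (log2 −1.45, adjusted p = 0.330), sox9b 14.8 ± 2.46 and 6.28 ± 2.11 (−1.15, 0.339), and sox9a 44.9 ± 14.2 and 22.1 ± 4.75 (−0.96, 0.350). After median centring lin28a was −0.99, sox9b −0.69 and sox9a −0.50, and smn1, at −0.46 as deposited, was 0.00.

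In the lin28a line, lin28a (ENSDARG00000016999) was 0.310, 1.23 and 0.866 TPM in 2Tg and 2.69, 8.41 and 3.16 in 3Tg. In the 2Tg groups of the other lines it was 5.48 ± 2.97 (smn1), 6.32 ± 1.68 (tardbp) and 6.59 ± 4.75 (sox9b). Another entry, LIN28A (ENSDARG00000004328), was 0.879, 0.711 and 0.399 in 2Tg and 1.46, 4.79 and 0.283 in 3Tg of this line. It was not tested here. In other gene groups 3Tg replicate 2 stood apart, with high inflammatory and low pancreatic genes. mmp9, a matrix protease of inflamed tissue, was 255 TPM in that library and 3.41 to 11.14 in the other 5. The log2 fold change of lin28a was 1.58 (SE 0.399), with adjusted p = 0.00776 over the 5 targets and 0.9795 over all genes in limma; it was 2.401 with a pseudocount of 0.1 and 0.71 with one of 5. No gene of 19580 passed limma over all genes, and 349 had an unadjusted p under 0.05 (137 higher, 212 lower; after median centring 188 higher, 178 lower), where 979 are given by chance; the smallest adjusted p was 0.572. The groups did not overlap in 6.56% of genes, where chance gives 10%.

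The list of LIN28 partners and targets of let-7, whose maturation LIN28 proteins block, had a median of 0.11 in the lin28a line, with 28 of 35 higher by sign (adjusted p = 0.00223; adjusted p = 0.664 with an estimated correlation). No member passed over the list alone. hmga2, a chromatin protein under let-7 control, was 28.2 ± 7.21 in 2Tg and 42.6 ± 17.95 in 3Tg, trim71 was 8.50 ± 1.07 and 14.5 ± 8.91, and the paralog lin28b was 4.70 ± 1.38 and 9.08 ± 5.93 (log2 0.68). igf2bp3 was 26.3 ± 1.197 and 26.0 ± 3.48. Without 3Tg replicate 2 the list median was 0.00 and the adjusted p 0.909, and relative to all genes it ranged over the leave-outs from 0.03 to 0.28.

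All 25 inflammation genes were higher by sign in lin28a 3Tg embryos (median 1.25, adjusted p = 5.41e-12), and all 28 exocrine pancreas genes were lower (−1.63, 4.85e-11). cxcl18b, a chemokine, was 1.96, 1.59 and 1.23 TPM in 2Tg and 4.25, 151 and 2.52 in 3Tg, and socs3b, a brake on cytokine signals, was 13.1, 8.88 and 8.50 in 2Tg and 19.5, 131 and 14.2 in 3Tg. amy2a was 636, 357 and 295 in 2Tg and 525, 3.59 and 104 in 3Tg. Immediate early genes had a median of 0.81 (1.28e-08), with junba at 54.0, 10.2 and 10.3 in 2Tg and 76.5, 309 and 18.2 in 3Tg. The intestine list had a median of −0.73 (1.20e-06), the neurons −0.56 (1.08e-07), ribosomal proteins 0.14 (1.57e-10) and mitochondrially encoded genes −0.30 (3.55e-06). The adjusted p of each was 0.664 with an estimated correlation, and no member of these lists passed over its list alone. Without 3Tg replicate 2 the medians were 0.21 for inflammation, −0.56 for exocrine pancreas, 0.50 for immediate early genes, −0.31 for intestine, 0.07 for ribosomal proteins and −0.24 for mitochondrially encoded genes, all past the test, and −0.07 for neurons (adjusted p = 0.433). Relative to all genes the medians ranged over the leave-outs from 0.24 to 2.07 for inflammation, −2.69 to −0.53 for exocrine pancreas, 0.37 to 1.52 for immediate early genes, −1.19 to −0.28 for intestine, −0.77 to −0.05 for neurons and 0.05 to 0.31 for ribosomal proteins. Without 3Tg replicate 1, 26 exocrine pancreas and 17 intestinal genes fell over the list alone, where none did with all libraries.

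In lin28a 8 further lists passed: endothelium (0.21, adjusted p = 6.66e-05), photoreceptors (−0.45, 2.47e-04), the unfolded protein response (0.23, 4.27e-04), neural crest (0.29, 0.00590), glia (−0.22, 0.00858), p53 targets (0.19, 0.0142) and heat shock (0.06, 0.0378), beside the list of let-7 targets and LIN28 partners. With an estimated correlation the adjusted p was 0.664 for each. Without 3Tg replicate 2 it was, at the preset correlation, 0.345 for endothelium and heat shock, 0.506 for photoreceptors, 0.240 for the unfolded protein response, 0.385 for neural crest and glia and 0.986 for p53 targets, the highest for each list over the leave-outs. The medians relative to all genes ranged from 0.05 to 0.36 for endothelium, −0.64 to −0.06 for photoreceptors, 0.06 to 0.44 for the unfolded protein response, 0.07 to 0.59 for neural crest, −0.31 to −0.08 for glia, 0.05 to 0.43 for p53 targets and 0.03 to 0.43 for heat shock. The other 20 lists did not pass (adjusted p 0.0821 to 0.886). Mitochondrially encoded genes made up 10.4% ± 1.57 of the nominal TPM total in 2Tg and 8.63% ± 0.356 in 3Tg (SD, n = 3; exact permutation p = 0.1, the smallest possible). That difference of −1.81 percentage points was −0.99997 without 2Tg replicate 3.

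The 8 genes of smallest p in lin28a, clone codes left aside, did not pass limma over all genes. They were hist1h4l (ENSDARG00000105382, adjusted p = 0.572) and 7 with an adjusted p of 0.9795. hist1h4l was 2.61, 3.19 and 2.91 TPM in 2Tg and listed at 0 in 3Tg. fthl27, a ferritin, was 15.5 ± 1.45 and 4.62 ± 2.06, asic4a 8.08 ± 0.422 and 3.02 ± 1.17, cyp2k6 6.37 ± 1.42 and 1.52 ± 1.34, and otofa, an otoferlin of hair cells, 14.1 ± 2.18 and 5.85 ± 1.95. ch25hl1.2 was 3.17 ± 1.07 and 0.757 ± 0.368, ftr53 2.84 ± 0.108 and 1.01 ± 0.179, and impg2b, of the matrix around photoreceptors, 3.198 ± 1.52 and 10.9 ± 3.90. Of the other named genes, sox9a was 27.3 ± 9.91 and 44.5 ± 11.9 (0.72, adjusted p = 0.9795).

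In the sox9b line, sox9b (ENSDARG00000043923) was 17.9 ± 0.675 in 2Tg and 35.3 ± 4.13 in 3Tg. Cartilage genes, several of them direct targets of SOX9 proteins, were close to their 2Tg level, as was the paralog sox9a. The cartilage collagen col2a1a was 432 ± 77.5 and 469.6 ± 89.7, and sox9a 54.3 ± 14.2 and 59.4 ± 3.26. The sox9b log2 fold change was 0.94 (SE 0.134), the third smallest p of 19619 genes, with adjusted p = 5.60e-04 over the 5 targets and 0.733 over all genes in limma. No gene passed limma over all genes and 239 had an unadjusted p under 0.05 (162 higher, 77 lower; after median centring 128 higher, 143 lower), where 981 are given by chance. The groups did not overlap in 4.75% of genes, where chance gives 10%.

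The cartilage list of the sox9b line had a median of 0.08, with 32 of 38 higher by sign, and did not pass (adjusted p = 0.348). col2a1b was 168 ± 18.9 and 192 ± 30.1, col11a1b 53.4 ± 3.87 and 63.3 ± 8.31, the matrix proteoglycan acana 9.79 ± 1.71 and 9.94 ± 2.44, and matn1 311 ± 61.3 and 312 ± 54.0. The bone list had a median of 0.20 (adjusted p = 0.0728), with col1a1a at 744 ± 91.3 and 980.0 ± 166. Without 2Tg replicate 3 both lists passed camera at the preset correlation, cartilage with a median of 0.19 (adjusted p = 1.84e-05) and bone with 0.14 (1.01e-04). With all libraries, no list of this line passed camera with an estimated correlation (lowest adjusted p = 0.788). No member of any list passed over its list alone.

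In sox9b 11 lists passed, with small medians. Ribosomal proteins were lower, with 69 of 81 lower by sign (median −0.04, adjusted p = 3.61e-08). Also lower relative to the other genes were minor spliceosome (−0.06), lens (−0.03), exocrine pancreas (−0.10) and hatching gland (−0.16), each with adjusted p = 0.0372, cell cycle (−0.01, 0.0383), and photoreceptors (−0.03), inflammation (−0.06) and immediate early genes (−0.06), each 0.0438. Neurons (0.12) and glia (0.11) were higher (0.0449). The adjusted p of each was 0.788 with an estimated correlation, none kept its call with every library left out, and 2 did after median centring. The highest adjusted p over the leave-outs was 0.271 for ribosomal proteins and 0.235 for the minor spliceosome without 2Tg replicate 3, 0.875 for exocrine pancreas and 0.229 for hatching gland without 3Tg replicate 3, and 0.306 for cell cycle without 2Tg replicate 1. It was 0.944 for photoreceptors without 3Tg replicate 1, 0.202 for lens and 0.974 for inflammation without 3Tg replicate 2, and 0.892 for immediate early genes, 0.554 for neurons and 0.794 for glia without 2Tg replicate 2. The other 24 lists did not pass (adjusted p 0.0718 to 0.844).

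Besides sox9b, the genes of smallest p in its line, clone codes left aside, did not pass limma over all genes. They were TMEM275 (adjusted p = 0.733) and 6 with an adjusted p of 0.9999. TMEM275 was 1.77, 2.00 and 1.92 TPM in 2Tg and listed at 0 in 3Tg. A second hist1h4l gene (ENSDARG00000105409) was 1.35, 2.29 and 1.48 in 2Tg and listed at 0 in 3Tg. pclaf, which binds the replication clamp, was 0, 1.51 and 0 in 2Tg and 3.33, 8.16 and 7.86 in 3Tg. MFAP4 was 2.14 ± 0.0928 and 0.474 ± 0.237, oc90, of the ear stones, 1.09 ± 0.395 and 3.50 ± 0.764, pomcb, a pituitary hormone precursor, 0.541 ± 0.325 and 2.73 ± 0.862, and adgrd1 2.48 ± 0.453 and 5.51 ± 0.719.

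Across 18656 genes tested in all lines, the fold changes of smn1 and tardbp went together (Pearson r = 0.54, Spearman rho = 0.49, across genes, which are not independent replicates), and the r was 0.343 without smn1 3Tg replicate 3 and 0.671 without smn1 3Tg replicate 1. At an unadjusted p under 0.05, 318 genes were lower in both lines, where 157 are given by chance, and 25 were higher in both, where 9.14 are. The direction of this overlap depended on scaling: after median centring 82 were lower in both (41.5 by chance) and 242 higher (83.5 by chance), and without tardbp 3Tg replicate 3, as deposited, 380 were lower (170 by chance) and 237 higher (56.5 by chance). For smn1 with lin28a the r was −0.29, but −0.121 without lin28a 3Tg replicate 2 and −0.164 without lin28a 2Tg replicate 1. For tardbp with lin28a it was −0.23, but −0.0773 without lin28a 3Tg replicate 3, −0.106 without lin28a 2Tg replicate 1, −0.135 without tardbp 2Tg replicate 1 and −0.141 without tardbp 3Tg replicate 1. It was 0.06, −0.03 and −0.03 for sox9b with smn1, tardbp and lin28a. No gene passed limma in 2 lines. In the tests of the difference between lines, 1 gene passed in the 6 pairs: vkorc1, of the vitamin K cycle, named after its values were seen (log2 −1.42 in tardbp and 0.46 in sox9b, difference −1.87, adjusted p = 0.0463). After median centring the vkorc1 difference was −1.35 (adjusted p = 0.761) and no gene passed in the 6 pairs; without tardbp 3Tg replicate 3 it was −1.80 (adjusted p = 0.0296), 1 of 2 genes past the test. Within smn1, tardbp and tardbpl were each −0.20, lin28a −0.21 and sox9b 0.52; within lin28a, sox9b was 0.42 and smn1 0.27; within sox9b, lin28a was −0.07.

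Genes beside the targets were examined because an activator may reach a neighbouring promoter. Of the 3 genes on either side of smn1, tardbpl and lin28a and the 3 on 1 side of sox9b, 14 were tested by limma and none had an unadjusted p under 0.05 (lowest 0.110). The others were not matched or did not pass the TPM filter. Among them were the genes directly beside the targets: nos2a and hspb11 (smn1), ciroz (tardbpl), ftr55 (lin28a) and sstr2b (sox9b). In the activation lines the only directly adjacent gene tested was pdik1l, beside lin28a (log2 −0.27, unadjusted p = 0.400 in limma). The neighbours of tardbp and those on the other side of sox9b were not analysed here.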

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

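In this part, the tests of whether a few genes took a large share of the TPM, of whether a sample was mislabelled, of tissue lists against 1 group alone, of how close the libraries were, of the hsp70l difference in smn1, of the differences between lines after centring, and of how much of a list's own median a slope removal left were chosen only after the result was seen.

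In several genes every 3Tg library lay above every 2Tg library in 1 line and below every 2Tg library in another. The genes looked at were the targets, their paralogs, the genes named for their smallest p and those past the test of the difference. asic4a differed by 2.02 on the log2 scale and otofa by 2.32 between smn1 and lin28a (adjusted p = 0.671 for each in limma). hist1h4l (ENSDARG00000105382) differed by −2.96 between smn1 and sox9b (0.998) and by −3.09 between lin28a and sox9b (1.00), and ftr53 by −1.34 between lin28a and sox9b (1.00) and by −1.52 between tardbp and sox9b (0.151). lin28a differed by −3.03 (0.112) and sox9a by −1.68 (0.123) between tardbp and lin28a. sox9b differed by −2.09 and tardbpl by −0.999 between tardbp and sox9b (0.151 for each). None of these genes passed the test of the difference. vkorc1 did, at −1.87 between tardbp and sox9b (adjusted p = 0.0463). The median of all genes was −0.45 in tardbp and 0.07 in sox9b, and after median centring the differences between these lines were −1.35 for vkorc1, −1.56 for sox9b, −0.47 for tardbpl and −0.999 for ftr53 (adjusted p = 0.761 for each). Those between tardbp and lin28a were then −2.62 for lin28a and −1.27 for sox9a (0.346 for each). The glia list was opposite in sign in the 2 lines where it moved in every library, with a median of 0.46 in smn1 and −0.22 in lin28a; their difference passed camera at the preset correlation (adjusted p = 3.43e-06; adjusted p = 0.631 with an estimated correlation).

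In the tardbp line 78.1% of genes were lowest in 3Tg replicate 3, which had a median log2 ratio of −0.99 to the other 5 libraries. A different mixture of tissues was tested after rescaling without zgc:158463, FO704772.3 and AL935186.10, which takes out a shift shared by all genes. Against the other 5 libraries, 0 of 18 tissue lists then lay beyond 1 on the log2 scale (exocrine pancreas −0.73, intestine −0.62). Those libraries mix both groups, which can hide opposite differences: exocrine pancreas was −3.33 against the other 3Tg libraries and 0.76 against 2Tg. Against 2Tg alone 0 lists lay beyond 1, and against the other 3Tg libraries 3 did (exocrine pancreas, intestine −1.64, erythrocytes 1.06). No list thus stood far from the common shift against 2Tg. A difference from its own group in those tissues is not excluded, and this test does not settle the cause of the shift. These 3 genes held 34.3% of the nominal TPM total and a further 22.2% was missing from the listed total; a few genes taking a large share of the TPM is consistent with the ratio of 0.00184 after that rescaling, which removes both losses at once. A mislabelled or non-responding sample stays open, since 1 of the 2 targets, tardbp, then lay within the 2Tg range and tardbpl did not: the median absolute deviation of log2 ratios was smaller to 2Tg replicates 3 and 2 (0.260 and 0.335) than to 3Tg replicates 1 and 2 (0.433 and 0.520), though not to 2Tg replicate 1 (0.448), and nr1d1 and amy2a lay within their 2Tg ranges, while he1.1 at 22.6 TPM stayed below the 2Tg range of 61.3 to 334. No biological explanation of that library was tested.

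hsp70l was lower in every smn1 3Tg library than in smn1 2Tg. The smn1 3Tg values lay within the range of tardbp 2Tg, and the smn1 2Tg values lay above every 2Tg library of tardbp and lin28a, though not of sox9b. The 2 number formats of the table are argued against as the whole cause, since the smaller difference within a format was −4.08, and so is scaling between libraries, since the smaller change under centring and quantile normalization was −4.11. An uneven heat response between collections cannot be told apart from an effect of the guide RNA: the difference was 2.37 standard errors when the spread of the other 6 groups (SD 2.16) was used, between the bounds of 2 and 4 set for that test. The groups of smn1 embryos themselves, with lower smn1, remain an open and untested explanation.

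The fold changes of smn1 and tardbp correlated across genes (r = 0.54, but 0.343 without smn1 3Tg replicate 3). Without tardbp 3Tg replicate 3 the r was 0.586, so that library does not account for it. Time of day cannot be told apart: the r was 0.528 after each gene's slope on a clock index was removed, but the slopes fitted in lin28a and in sox9b correlated at only 0.255, the removal left 75.9% of the clock genes' own median in smn1 and 56.1% in tardbp, and the clock lists lay above all genes in both lines. Nor can developmental stage be told apart, since removing the cell cycle slope (r = 0.553 after) left 135% of the cell cycle genes' own median in smn1 and 65.0% in tardbp, and the medians of the pancreas, intestine and photoreceptor lists lay above that of all genes in both lines. An effect shared by the knockdown system or by the targets, and other differences between siblings, stay open and untested. The number formats were uneven in both lines, with 6 significant digits in more 3Tg than 2Tg libraries. Their part in the correlation was not tested either.

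The 6 libraries of a line can be divided in 10 ways, too few for a share under 0.05. In smn1 the real division gave 2421 genes at an unadjusted p under 0.05 and the highest other split 2337, so that no other split gave as many. The split with 2337 genes follows the number format. With the format as a covariate, 2202 genes had an unadjusted p under 0.05 and no gene passed limma. In tardbp the real value was 2657 and the highest other 2132, so that again no other split gave as many. In lin28a the values were 349 and 2699, and in sox9b 239 and 2101. As many genes as in the real division came from 6 splits in lin28a and all 10 in sox9b, the real one included. Other splits called up to 108 genes in smn1, 429 in tardbp and 13 in lin28a, where the real ones called 0, 2 and 0, which points to a structure of the samples other than the groups.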

How the results depend on the processing

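Among the alternatives here, the number format as a covariate, centring without tardbp 3Tg replicate 3, and centring, rescaling and leave-outs of the gene lists were chosen only after the data were seen; the others were planned. Of 92 target fold changes under the alternatives, 87 kept direction and side of the threshold and 5 gained the call over all genes. Those were tardbp at −0.62 and tardbpl at −0.73 with array weights and −0.89 and −0.93 in one fit over all 24 libraries, and sox9b at 0.94 with array weights. Called genes in smn1 numbered 10 with array weights, 5 with no trend in the variance prior, 5 at an adjusted p under 0.1 and 0 to 2 in leave-outs. In tardbp, with 2 called, the number was 0 with a pseudocount of 0.1, no filter on low values, median centring, quantile normalization or the rescaled total, 28 with the replicate block, 8510 with array weights, 10 with a robust variance prior, 3293 in one fit over all 24 libraries, 35 with centring without 3Tg replicate 3, 5 at an adjusted p under 0.1 and 0 to 176 in leave-outs. In sox9b it was 27 with array weights, which did not converge there or in tardbp. The replicate block called 0 genes in the other lines. The sample labels give replicates a number and name no pairing. By the median absolute deviation of log2 ratios, the 2Tg and 3Tg replicates 1 of lin28a (0.157) and of sox9b (0.162) were the closest libraries. Correlations of deviations from the group mean between libraries of the same number ran from −0.338 (sox9b replicate 2) to 0.376 (lin28a replicate 1). A pairing in some lines is thus not excluded. Lists past the test numbered 0 with an estimated correlation and 0 with fry in all 4 lines, 2 in sox9b with median centring, and in leave-outs 7 to 19 in lin28a and 4 to 17 in sox9b.

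Camera's direction changed in leave-outs for the following lists, whose medians relative to all genes ranged from 0.0203 to 0.25 for smn1 ribosomal proteins and 0.0514 to 0.43 for lin28a p53 targets. In sox9b they ranged from −0.26 to 0.0596 for cell cycle, −0.26 to 0.00826 for photoreceptors, −0.18 to 0.0106 for lens, −0.54 to 0.12 for exocrine pancreas, −0.31 to 0.16 for inflammation, −0.21 to 0.0597 for immediate early genes, −0.0538 to 0.14 for glia and −0.20 to 0.00952 for ribosomal proteins. Raw medians changed sign in other lists, such as in tardbp without 3Tg replicate 3 from −0.09 to 0.35 for heat shock, −0.16 to 0.30 for neurons, −0.22 to 0.13 for glia, −0.23 to 0.14 for muscle stress, −0.26 to 0.15 for ribosomal proteins, −0.03 to 0.32 for leukocytes and −0.03 to 0.07 for the interferon response, and in lin28a without 3Tg replicate 2 from 0.11 to −0.00333 for let-7 targets and LIN28 partners, with camera's direction unchanged. Shares in percentage points ranged from −0.280 to 0.248 (smn1), −2.06 to 1.32 (tardbp), −2.57 to −0.99997 (lin28a) and −0.613 to 0.191 (sox9b) for mitochondrially encoded genes, and from −0.269 to 1.91 (smn1), 3.24 to 8.22 (tardbp), −0.154 to 0.802 (lin28a) and −1.53 to 0.0694 (sox9b) for the 100 most abundant genes. Correlations of fold changes ranged from −0.0273 to 0.18 for smn1 with sox9b, −0.16 to 0.0830 for tardbp with sox9b and −0.21 to 0.16 for lin28a with sox9b. The cause was not tested for any of these. Of 561 values of named genes, 504 kept direction and side of the threshold, 14 lost the call and 43 gained it. Among the named genes only he1.2 and he1.1 had a call to lose, so all 14 losses were theirs. lin28a and PCP4 have no value with a TPM minimum of 5, and the planned tests by chromosome were not run. Depth is unknown, so what it limits was not assessed.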

Other observations

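The contents of this part, other than the counts of neighbouring genes, were chosen after the data were seen.

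Heat shock and clock genes varied between libraries of 1 group in several lines. hsp70l was 10.6, 6.45 and 13.8 TPM in lin28a 2Tg and 7.21, 1137 and 44.3 in 3Tg, 181, 464 and 20.1 in sox9b 2Tg and 394, 54.9 and 25.9 in 3Tg, and 13.1, 38.3 and 4.55 in tardbp 2Tg and 36.1, 8.61 and 120 in 3Tg. Its 1137 TPM in lin28a 3Tg replicate 2 stood in the library with the highest mmp9 and cxcl18b. nr1d1 was 33.8, 5.91 and 3.05 TPM in lin28a 2Tg and 46.4, 32.7 and 3.12 in 3Tg, 4.26, 5.53 and 2.37 in smn1 2Tg and 4.47, 50.3 and 11.6 in 3Tg, and 5.23, 11.9 and 1.24 in sox9b 2Tg and 5.17, 2.03 and 13.0 in 3Tg. The split of the lin28a libraries that sets the 3 with nr1d1 above 30 TPM against the others gave 2699 genes at an unadjusted p under 0.05.

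In smn1, hsp70.1, hsp70.2 and hsp70.3 lie next to each other in the genome and made up both of its 2 adjacent pairs of genes with an unadjusted p under 0.001. In 10000 shuffles of the 52 such genes the mean number of pairs was 0.153 and the highest 3, and 0.0102 of the shuffles gave as many. In tardbp the single pair was he1.1 and he1.2 (0.0818 of shuffles). All 3 of these pairs share a gene-family name. At an unadjusted p under 0.01 there were 15 pairs in smn1 (mean 11.9 in shuffles, 0.217 of which gave as many) and 20 in tardbp (mean 15.06, 0.1196 of shuffles). In lin28a and sox9b 0 and 2 genes had an unadjusted p under 0.001, so that adjacency was in effect not tested there.

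Genes listed at 0 numbered 2649 ± 182 in smn1 2Tg libraries and 3270.0 ± 108 in 3Tg (SD, n = 3, exact permutation p = 0.1, the smallest possible). The number formats are uneven here. With 6 decimals the numbers were 2587 and 2507 in 2Tg and 3360 in 3Tg, and with 6 significant digits 2854 in 2Tg and 3300 and 3150 in 3Tg. In other lines they ran from 2543 to 3150 in sox9b, all with 6 decimals, and from 3087 to 3311 in lin28a, all with 6 significant digits. Depth, which also bears on them, is unknown. The 100 most abundant genes held 38.7% ± 1.22 of the TPM in tardbp 2Tg and 45.2% ± 5.64 in 3Tg (exact permutation p = 0.1); the difference of 6.49 percentage points was 3.24 without 3Tg replicate 3. With fry's test of change in either direction, 6 smn1 lists passed, with the lowest adjusted p, 7.35e-04, in neurons; no list passed in the other lines.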
